A study of Arabidopsis thaliana with 12 samples.

How the data were processed

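ATAC-seq libraries of Arabidopsis thaliana roots were analysed in 4 groups of 3 libraries: uncut roots, and roots 2.5 h, 14 h and 16 h after the tip was removed. Per the labels' protocols, the cells were released by digesting the wall and sorted on GFP or DAPI, nuclei were treated with Tn5, and the number of PCR cycles was chosen per library by qPCR. Groups and replicate numbers were taken from the sample labels.

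The files hold raw read counts per accessible region in whole numbers, as deposited by the authors, 1 file per library. Tables of the authors give, for each time against uncut roots, a normalized signal per library, which per the file headers goes with a log2 fold change and a p-value per region, and a distance to the nearest transcription start (TSS). Bowtie2, SAMtools, MACS2, DESeq2 and HOMER, and the genome build TAIR10, are named in the submitters' processing notes with no version. Removal of duplicate reads, the counting tool and the settings of the peak caller are not given in the sources used here. The signal in the deposited tables was found to be whole reads divided by a size factor: at a tolerance of 0.01, 100% of the values came out whole. PCR copies of a fragment may be counted more than once, and intervals and floors here cover counting error only.

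Regions differ between groups. The uncut and 16 h files share 107842 regions, the 2.5 h files hold 116892 and the 14 h files 136932. Each comparison used the regions with identical coordinates in both groups: 103844 for 2.5 h and uncut, 101676 for 14 h and uncut, 107842 for 16 h and uncut, 99165 for 14 h and 2.5 h, 103844 for 16 h and 2.5 h, and 101676 for 16 h and 14 h. The median width was 135 bp in the uncut set, and 0 regions lay on the organelle genomes. Whether reads at nuclear regions also match organelle or repeated sequence was not examined. Regions present in the set of a single group were left out of the main tests. A gene was taken from the authors' tables of 2.5 h and 14 h for 137819 of 156035 distinct regions, from an overlapping annotated region for 8017, and from an annotated region at most 500 bp away for 6752, and 3447 had none. The gene column of the 16 h table matched that of the 14 h table for 33.8% of shared regions and was not used. Of the gene names, 20 had been turned into dates and were resolved through the aliases of the reference table.

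Libraries held between 1.44 M and 31.8 M reads in regions. A count of 0 allows up to 3 counts, or 0.0944, 0.118 and 0.134 CPM (counts scaled to a common library size) in the uncut libraries, 0.628, 1.03 and 1.64 at 2.5 h, 0.266, 0.280 and 0.173 at 14 h, and 1.78, 1.28 and 2.09 at 16 h.

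Each of the 6 comparisons was tested with edgeR 4.0.16 (R 4.3.3) on the counts of its 6 libraries: TMM normalization, the filterByExpr filter, the quasi-likelihood F test and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. Levels in CPM use the TMM library sizes of that comparison, so that a gene's level in uncut roots differs slightly between comparisons. Counts were also summed per gene and tested in the same way. The 15 gene lists cover wound and regeneration transcription factors, early stress and immune response, jasmonate, ethylene, auxin, cytokinin, cell cycle and DNA replication, the root stem cell niche, root cap and columella, vascular and stele, epidermis and root hair, endodermis and cortex, heat shock, chromatin regulators, and photosynthesis as a marker of leaf cells. They hold 334 genes, of which 329 had a region. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), which compares a list with the other genes, and with fry.

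The groups, the tests, the gene lists, most alternatives and the rule for named genes were set before the data were examined. The rule names MP in every library first. It then takes, against uncut roots, the 6 regions higher and 6 lower (4 and 4 between times) with the largest absolute log2 fold change among those that pass, lie above the median level and separate the groups completely, 1 per gene. It also takes up to 4 members of each list with the smallest p. Where fewer regions passed, fewer are named.

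Alternatives were DESeq2 1.42.0, its size factors within edgeR, total counts without TMM, no filter, the replicate number as a block, a test against an absolute log2 fold change of 1, all 12 libraries in the fit, each library left out in turn, sums over regions within 1 kb of a TSS, and camera with an estimated correlation. Those limited to chromosomes 3 and 5, all gene-count alternatives, and all regions of the 14 h set with recovered reads were added after seeing the data. A scaling choice moved the median log2 fold change of all regions by more than 0.1 for 2.5 h against uncut (-0.38 with TMM, -0.22 with DESeq2 size factors, -0.06 with total counts), 14 h against 2.5 h (0.39, 0.26 and 0.11) and 16 h against 2.5 h (0.24, 0.20 and 0.06), and changes in these comparisons are relative to TMM. Each test was run first on simulated counts with 100 features changed per fold size. Where the real data hold many more changes, the adjustment is less strict than in these simulations. The shares recovered therefore do not give the power of the comparisons with uncut roots. Changes of 2-fold were recovered in 0%, 52% and 52% of genes against uncut roots and in 0%, 0% and 24% between times. Motif tests and a GC correction need a genome sequence and were not run. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.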

Results

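Chromatin accessibility was profiled by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open DNA, in Arabidopsis thaliana roots that were regrowing a removed tip. Seedlings were taken at 7 DAS, about 130 µm of the tip was cut away, and the next 200 µm or so above the wound was collected 2.5 h, 14 h or 16 h later. Uncut roots of the Col-0 accession gave a segment of matching size. Each of the 4 groups held 3 libraries, 12 in all. Regenerating cells came from plants with a MP::MP-GFP transgene and were sorted on GFP, 1000 nuclei per library (2000 in 16 h replicate 3), whereas uncut cells were stained with DAPI and 50000 nuclei were used. MP, or MONOPTEROS, is an auxin response factor active in the root vasculature. A comparison with uncut roots therefore changes the plant line, the sort and the number of nuclei together with excision, and a comparison between times does not, apart from the nuclei of 16 h replicate 3.

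Reads in accessible regions numbered 31.8, 25.3 and 22.5 M in the uncut libraries, 4.78, 2.90 and 1.83 M at 2.5 h, 11.3, 10.7 and 17.3 M at 14 h, and 1.69, 2.35 and 1.44 M at 16 h. The uncut and 16 h libraries were counted over 107842 regions, the 2.5 h libraries over 116892 and the 14 h libraries over 136932. Regions without a single read made up 26.9%, 26.1% and 35.1% of the set in the 2.5 h libraries, 5.36%, 2.11% and 2.39% at 14 h, 4.14%, 6.13% and 4.82% at 16 h, and at most 0.0204% in uncut roots. Spearman correlations between replicates, taken across regions, ran from 0.937 to 0.957 in uncut roots, from 0.277 to 0.317 at 2.5 h, from 0.556 to 0.651 at 14 h and from 0.483 to 0.513 at 16 h. Replicates of every group differed by more than sampling noise, with a chi-square per degree of freedom of 2.51 or more, so none was taken for another library deposited again. Copies of a fragment made in PCR also raise this value, which therefore does not show that the libraries came from separate material. The labels do not say whether replicates came from separate batches of plants, and p-values measure only the spread between these libraries. The tests take a single spread per region or gene for both groups compared. Since replicates were more alike in uncut roots, p-values against uncut roots can understate the spread of the regenerating libraries.

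MP itself (AT1G19850, chromosome 1, 6881528 to 6890565, TAIR10, 11 regions counted in every library) stood at 98.5 ± 4.31 CPM in uncut roots (mean ± SD, n = 3). The level was 290 ± 65.0 CPM at 2.5 h, 295 ± 7.81 CPM at 14 h and 270 ± 61.4 CPM at 16 h, ratios to uncut roots of 2.95, 3.0 and 2.74. All 9 regenerating libraries lay above all 3 uncut libraries. In the gene-level test MP rose by log2 1.46 ± 0.11 (SE) at 14 h (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.96e-05) and by 1.5 ± 0.18 at 16 h (adjusted p = 0.000692). At 2.5 h the log2 fold change of 1.51 ± 0.22 missed the threshold (edgeR adjusted p = 0.0748, and 0.0105 adjusted over the list alone), which it passed without 2.5 h replicate 1, 2 or 3 (0.0317, 0.0238 and 0.0243) and missed further without uncut replicate 1, 2 or 3 (0.447, 0.542 and 0.538). MP is also the gene of the transgene in this line. Whether reads from the transgene add to its level was not examined. Here and below, folds of MP against uncut roots therefore need not measure accessibility.

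**Figure D1:**
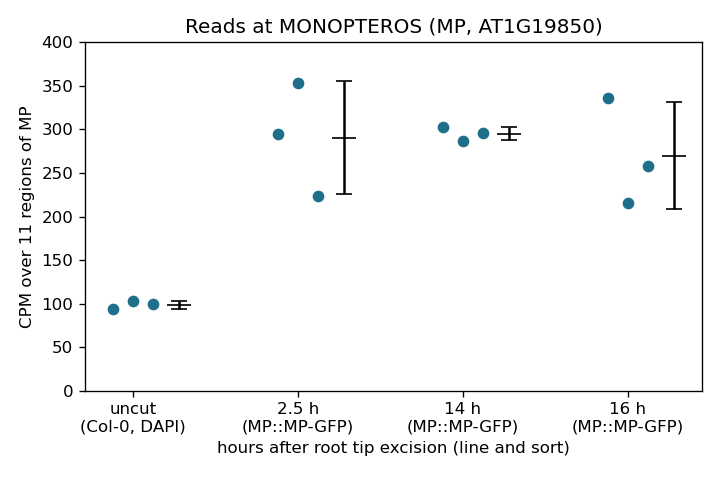
Reads at MP in CPM (vertical axis) for the 3 libraries of each group (points), with the group mean and SD (black bars), against the time after excision. The uncut libraries lie between 93.9 and 102 CPM and the regenerating libraries between 215 and 353 CPM.

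The first comparison asked how accessibility at 2.5 h after excision differed from uncut roots. Among regions that rose were exon 8 of MP (chromosome 1, 6888766 to 6888899), at 51.7 ± 26.6 CPM against 8.56 ± 1.68 CPM and a log2 fold change of 2.59 ± 0.45, and the 3' end of CBL2 (AT5G55990, a calcineurin B-like calcium sensor, chromosome 5, 22674041 to 22674129), at 21.3 ± 2.45 against 4.10 ± 0.42 CPM and 2.37 ± 0.37. Regions at AT1G40104 (an intron, 2.55), AT2G27780 (2.49) and AT3G08300 (2.40) rose by similar log2 amounts. So did a region in exon 54 of AT3G48190 (2.36), for which the nearest TSS is that of AT3G07885 (distance -9535 bp). Regions that fell included the first exon of PDIL1-5 (AT1G52260, a protein disulfide isomerase-like protein), at a log2 fold change of -4.80 ± 1.05, from 30.3 ± 1.40 CPM to 1.21 ± 1.11 CPM, and an intergenic region upstream of AT4G06598, a bZIP family gene (chromosome 4, 3651841 to 3652493), at -4.08 ± 0.38, from 45.3 ± 8.70 to 2.62 ± 0.89 CPM. The other named regions that fell lay near AT4G04077 (-4.66), AT4G30770 (-4.39) and AT4G11870 (-4.26), and on chromosome 2 from 4181523 to 4182077 with no gene assigned (-4.34), and all 6 lay on chromosomes 1, 2 and 4. Without 1 of the uncut libraries at a time, 11 of these 12 regions missed the threshold (edgeR adjusted p between 0.0724 and 0.244), the exception being the region near AT4G06598. PDIL1-5 and AT4G11870 also missed it without 2.5 h replicate 2 (0.0547 and 0.0600), AT4G04077 without replicate 1 (0.0549), and AT3G08300 without replicate 2 or 3 (0.0572 and 0.0516).

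Of 103746 regions tested between 2.5 h and uncut roots, 48 were higher and 7994 lower at an adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), and DESeq2 called 301 and 5839. The median region lay at a log2 fold change of -0.38. Of the regions called lower, 91.6% had no read in any 2.5 h library. On chromosomes 3 and 5 this held for 1704 of 1904. Zeros falling independently in the 3 libraries, at matched uncut level, would alone put 1603 regions of these chromosomes at 0 in all 3. Most of the lower calls there therefore need not reflect lower accessibility. Counts moved with each library: without uncut replicate 1, 2 or 3 there were 1, 0 and 0 regions higher and 3943, 3514 and 3420 lower, and without 2.5 h replicate 1, 2 or 3 there were 1108, 1211 and 1391 higher and 16988, 17679 and 14649 lower. Summed per gene, 2 of 28729 genes were higher and 57 lower. The genes higher were EMB2820 (AT5G24670, a cytidine and deoxycytidylate deaminase family gene), with a log2 fold change of 2.34 ± 0.28, and AT2G41590, with 2.06 ± 0.19; both were named after their values were seen. Without any 1 uncut library no gene was higher or lower (0 and 0), and without 2.5 h replicate 1, 2 or 3 there were 381, 454 and 477 genes higher and 1382, 1376 and 1315 lower.

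None of the 15 gene lists fixed beforehand passed camera at 2.5 h (lowest adjusted p = 0.140), and 0 of their 325 measured members were higher and 0 lower over all genes tested by edgeR, where 2856 genes had an unadjusted p under 0.05. Adjusted over the list alone, 3 members were higher and 3 lower. CKX1 had no read at 2.5 h, and the other 5 were MP, the type-A cytokinin response regulators ARR9 (54.2 ± 10.1 against 22.2 ± 2.86 CPM, log2 fold change 1.29 ± 0.26) and ARR4 (53.0 ± 3.49 against 25.8 ± 2.62 CPM, 1.04 ± 0.22), the epidermal patterning factor GL2 (7.86 ± 1.5 against 28.6 ± 3.94 CPM, -1.85 ± 0.37) and the root hair cell wall protein gene PRP3 (31.8 ± 5.02 against 63.7 ± 3.15 CPM, -1.0 ± 0.21). In libraries simulated for this comparison, changes of 4-fold were recovered in 0% of the altered genes and 0% of the altered regions.

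The second comparison, 14 h against uncut roots, addressed a later stage of the regrowth. JAZ6, JAZ10 and MYC4, of the jasmonate response, rose by log2 1.25 ± 0.31, 0.94 ± 0.23 and 0.96 ± 0.17, and CDKB1;2, a cyclin-dependent kinase of mitosis, rose by 1.29 ± 0.21, from 17.62 ± 1.86 to 43.2 ± 11.4 CPM. LHCB1.1, a light-harvesting protein gene, fell by 1.02 ± 0.15, from 37.7 ± 0.757 to 18.6 ± 1.25 CPM, and ESB1, which acts in the Casparian strip of the endodermis, fell by 0.85 ± 0.12, from 84.4 ± 6.65 to 46.8 ± 3.29 CPM. Over all genes, 820 of 28474 were higher and 2163 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Without uncut replicate 1, 2 or 3 there were 25, 36 and 54 genes higher and 879, 964 and 1096 lower. Without 14 h replicate 1, 2 or 3 there were 2248, 1837 and 1550 higher, and 3390 lower without replicate 1.

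Across the lists at 14 h, 16 members were higher, 16 lower, and the rest of 324 did not pass. Over all 28474 genes tested, 820 were higher and 2163 lower. Taken in both directions together, list members passed at about the share of all genes, with relatively more of them higher. Adjusted over the list alone the counts were 25 and 23. The cytokinin list held 5 members that rose and 3 that fell, with 23 that did not pass (5 and 3 adjusted over the list alone). Its receptor AHK2 rose by 0.71 ± 0.15, ARR9 by 0.71 ± 0.17 and the synthesis gene IPT7 by 0.58 ± 0.13, and the response regulator ARR1 fell by 0.68 ± 0.13. In the auxin list 2 rose, MP and the influx carrier AUX1 (0.90 ± 0.23), 1 fell, the synthesis gene TAA1 (-0.82 ± 0.15), and 34 did not pass (4 and 3 adjusted over the list alone). The jasmonate list gave 3 higher, 0 lower and 21 that did not pass (3 and 1), and the ethylene list 0 higher, 1 lower, the receptor ETR2 (-0.92 ± 0.18), and 19 that did not pass (0 and 1). Among wound and regeneration transcription factors 1 rose, LBD29 (1.02 ± 0.22), 1 fell, LBD18 (-0.60 ± 0.14), and 20 did not pass (1 and 1). In the early stress and immune list 1 rose, the peptide precursor PROPEP3 (1.07 ± 0.27), 3 fell, PR5 (-0.87 ± 0.20), PR2 (-0.69 ± 0.17) and GLR3.6 (-0.57 ± 0.15), and 26 did not pass (2 and 4). The pathogenesis-related PR genes are markers of salicylate-linked defence.

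For the cell cycle list, CDKB1;2 and CYCA2;1 (1.29 ± 0.35) rose, 0 fell and 36 did not pass at 14 h (1 and 0 adjusted over the list alone). Chromatin regulators gave 1 higher, the DNA methyltransferase CMT3 (0.51 ± 0.13), 2 lower, the histone deacetylase HDA19 (-1.0 ± 0.20) and the remodeller BRM (-0.56 ± 0.12), and 13 that did not pass (3 and 2). Summed only over regions within 1 kb of a transcription start, BRM and CMT3 turned to 0.09 and -0.02, neither past the threshold. Of the markers of root tissues, FEZ rose (0.66 ± 0.14) and 7 root cap genes did not pass (1 and 0), GL2 fell (-0.55 ± 0.14) and 12 epidermis genes did not pass (3 and 2), ESB1 and CO2 (-0.67 ± 0.16) fell and 13 endodermis and cortex genes did not pass (2 and 3), and 0 of 12 stem cell niche genes and 0 of 34 vascular genes passed (0 in either direction for both lists). Heat shock genes gave 0 of 15 in each direction (0 and 0). Of the photosynthesis list, a marker of leaf cells, LHCB1.1 and LHCB1.2 (-0.77 ± 0.18) fell and 7 did not pass (0 and 3). LHCB1.1 and LHCB1.2 are near-identical neighbours, so short reads cannot always be told apart between them. Both lie on chromosome 1, where 6.59% of the regions tested at 14 h were lower, against 1.91% on chromosomes 3 and 5.

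No list passed camera at 14 h (lowest adjusted p = 0.453), but with only regions within 1 kb of a transcription start 1 list did, photosynthesis, at adjusted p = 0.0198, which an estimated correlation on the same regions brought to adjusted p = 0.434. With an estimated correlation over all regions the lowest adjusted p was 0.571. Of the 28 list members that passed edgeR and were named at 14 h, 25 lost the call without 1 of the uncut libraries (adjusted p up to 0.266), 7 of these also without a 14 h library. MP, ESB1 and LHCB1.1 passed in each of these fits. Within 1 kb of a transcription start 23 of the 28 could be measured, and 14 of these lost the call or turned.

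Named regions were those past the threshold with a level above the median and no overlap between the groups, 1 per gene. The named region with the largest rise at 14 h lay near AT2G07981 on chromosome 2 (3605705 to 3606034, intergenic), from 11.7 ± 0.60 to 438 ± 33.4 CPM, a log2 fold change of 5.23 ± 0.14 (edgeR adjusted p = 5.51e-05), followed by an intron of AT2G08986 (3620335 to 3620633, 3.08 ± 0.13). The region at AT2G07643 (chromosome 2, 3404882 to 3405051) rose by 2.78 ± 0.53. Whether reads at these regions of chromosome 2 also match organelle or repeated sequence was not examined, so their folds need not measure accessibility. EMB2820 (chromosome 5, 8447574 to 8447739, promoter) rose from 8.66 ± 1.24 to 37.6 ± 3.65 CPM, a log2 fold change of 2.12 ± 0.19, an intergenic region of chromosome 5 (11707496 to 11707571) rose by 2.12 ± 0.19, and the promoter of AT2G34610 by 2.20 ± 0.43. The named regions that fell were all intergenic and all on chromosomes 1, 2 and 4, nearest to AT1G06963 (chromosome 1, 13513236 to 13514548, from 91.5 ± 17.63 to 3.33 ± 1.27 CPM, -4.81 ± 0.32), the AP2 family gene RAP2.9 (-4.35 ± 0.21), AT4G05555 (-4.24), AT1G36230 (-4.21), AT2G12945 (-4.04) and AT4G05705 (-3.92). AT2G07643 missed the threshold without uncut replicate 3 or 14 h replicate 3 (edgeR adjusted p = 0.0910 and 0.0525), AT2G34610 without uncut replicate 1, 2 or 3 (0.164, 0.122 and 0.108), and AT4G05705 without uncut replicate 1 (0.0677).

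Between 14 h and uncut roots 779 of 101666 regions were higher and 5326 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and DESeq2 called 7289 and 11786. With all 12 libraries in the fit edgeR called 18 and 2285. The regions tested are those with identical coordinates in both sets. Over all 14 h regions, with reads recovered from the authors' normalized columns after the data were seen, 25855 were higher and 16050 lower, in a set that includes regions found at 14 h and not in uncut roots. Without uncut replicate 1, 2 or 3 the counts were 40, 38 and 48 higher and 2711, 2935 and 3058 lower. Without 14 h replicate 1, 2 or 3 there were 4633, 3203 and 2535 higher, and 10227 lower without replicate 1. In simulated libraries of this comparison 93% of genes and 2% of regions changed by 4-fold were recovered.

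The comparison of 16 h with uncut roots covered the latest time. JAZ10, a repressor of jasmonate responses, rose by log2 1.71 ± 0.23, from 8.45 ± 1.27 to 27.3 ± 4.18 CPM (edgeR adjusted p = 0.00142). ARR7, a type-A cytokinin response regulator, rose by 1.47 ± 0.25, from 6.60 ± 0.29 to 18.5 ± 3.24 CPM, and ANAC071, a NAC factor of wound healing, by 1.86 ± 0.46, from 3.45 ± 0.36 to 12.03 ± 8.57 CPM. Without 16 h replicate 2 the log2 fold change of ANAC071 stood at 1.097 and that of WRKY18, a stress-response factor, at 0.70 in place of 1.49, and neither passed. JAZ6 (1.05 in place of 1.61), ERF109 (0.63 in place of 0.95), AOC3, IAA2, JKD and GL2 did not pass without that library either. ESB1 fell by 0.97 ± 0.22 and BRM by 0.88 ± 0.19. Of 28939 genes tested by edgeR, 990 were higher and 1763 lower at an adjusted p under 0.05. Without uncut replicate 1, 2 or 3 there were 88, 105 and 111 genes higher and 572, 636 and 694 lower. Without 16 h replicate 1, 2 or 3 there were 1553, 1994 and 1986 higher, and 2830 lower without replicate 2.

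Across the lists at 16 h, 22 members were higher and 10 lower of 325 measured, with JKD counted in both of its lists. Over all 28939 genes tested, 990 were higher and 1763 lower. Here too, list members passed in both directions together at about the share of all genes, with relatively more of them higher. Adjusted over the list alone the counts were 25 and 11. The jasmonate list gave 3 higher, JAZ10, JAZ6 (1.61 ± 0.40) and the synthesis gene AOC3 (0.70 ± 0.17), 1 lower, the lipoxygenase LOX6 (-0.70 ± 0.15), and 20 that did not pass (3 and 1 adjusted over the list alone). In the wound list ANAC071 and ERF109 (0.95 ± 0.26) rose, LBD18 fell (-0.57 ± 0.15) and 19 did not pass (2 and 1). Of the early stress and immune genes, PROPEP3 (1.13 ± 0.25) and WRKY18 (1.49 ± 0.38) rose, PR5 (-0.79 ± 0.20) and PR1 (-0.64 ± 0.17) fell and 26 did not pass (2 and 2). Ethylene genes gave 2 higher, ERF5 (0.89 ± 0.20) and the synthesis gene ACS8 (0.71 ± 0.17), 0 lower and 19 that did not pass (2 and 0). In the auxin list MP, IAA30 (0.67 ± 0.15) and IAA2 (0.74 ± 0.21) rose, GH3.2 fell (-0.59 ± 0.15) and 33 did not pass (3 and 2). GH3.2, an auxin-conjugating enzyme, stood at 0.07 when only regions within 1 kb of a transcription start were summed. The cytokinin list held 3 that rose, ARR7, ARR8 (0.85 ± 0.21) and IPT7 (0.56 ± 0.15), 1 that fell, IPT3 (-0.62 ± 0.15), and 27 that did not pass (3 and 1).

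CYCB2;1 (1.19 ± 0.25) and CYCB1;2 (0.94 ± 0.21), B-type cyclins of mitosis, rose at 16 h, 0 cell cycle genes fell and 36 did not pass (2 and 0 adjusted over the list alone). JKD (0.75 ± 0.19), which restricts SHR movement in the ground tissue, rose and stands in both the stem cell niche list, where 0 fell and 11 did not pass (1 and 0), and the endodermis and cortex list, where ESB1 fell and 13 did not pass (4 and 1). CLE41 (0.95 ± 0.20), a vascular peptide gene, rose while 0 vascular genes fell and 33 did not pass (1 and 0). GL2 fell (-0.67 ± 0.18) and 12 epidermis genes did not pass (0 and 0), and 0 of 8 root cap genes passed in either direction (0 and 0). The heat shock list gave HSP90.1 (0.67 ± 0.17) and HSP22 (0.79 ± 0.22) higher, 0 lower and 13 that did not pass (2 and 0). Chromatin regulators gave 0 higher, BRM lower and 15 that did not pass (0 and 1), and photosynthesis genes 0 higher, LHCB1.1 lower (-1.05 ± 0.23) and 8 that did not pass (0 and 2).

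No list passed camera at 16 h (lowest adjusted p = 0.404). Of the 31 list members that passed edgeR and were named at 16 h 29 lost the call without 1 of the uncut libraries (adjusted p up to 0.2802), 13 of these also without a 16 h library. JAZ10 and MP passed in each of these fits. Within 1 kb of a transcription start 25 of the 31 could be measured, and 14 of these lost the call or turned.

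Among the regions named at 16 h, picked as at 14 h, the largest rises lay at U6 small nuclear RNA genes. U6-26 (AT3G13855, chromosome 3, 4561198 to 4561389) stood at 0.981 ± 0.10 CPM in uncut roots and at 1526, 97.4 and 1790 CPM in the 16 h libraries, a log2 fold change of 10.17 ± 1.09, and U6-29 (AT5G46315, chromosome 5, 18787070 to 18787402) at 3.32 ± 0.69 CPM and at 2203, 141 and 2835 CPM (9.02 ± 1.07). With total counts as library sizes, replicate 2 held 5.37% (U6-26) and 5.05% (U6-29) of the mean excess of replicates 1 and 3. The source of this unevenness was not tested, so these folds need not measure accessibility. An unassigned region of chromosome 5 (11737441 to 11737517) rose by 6.10 ± 0.40 and AT2G07698 by 5.85 ± 0.53. Whether reads at these regions also match other sequence was not examined. On chromosome 5, a region at LSU4 (AT5G24655, a gene of the low-sulfur response family, 8442185 to 8442233) rose from 0.857 ± 0.26 to 43.8 ± 11.3 CPM (5.67 ± 0.32) and a region at EMB2820 (8449610 to 8449697) from 1.18 ± 0.39 to 45.7 ± 6.21 CPM (5.27 ± 0.30). Regions that fell included UBQ11 (AT4G05050, a polyubiquitin gene, exon 2, chromosome 4, 2588259 to 2588905), from 34.8 ± 0.15 to 1.27 ± 0.88 CPM (-4.77 ± 0.38), the promoter of AT2G16586 (-5.36 ± 0.49) and an exon of AT2G24945 (-3.88). The others were intergenic, nearest to AT1G42190 (-5.69 ± 0.51), AT1G06963 (-4.03 ± 0.34) and AT4G06639 (-3.92), at distances of 40854, 12806 and -17917 bp from the TSS. All 6 lay on chromosomes 1, 2 and 4. UBQ11 belongs to a family of near-identical copies among which reads can be split.

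In all, 3310 of 107749 regions were higher and 7100 lower at 16 h than in uncut roots (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and DESeq2 called 8181 and 10614. With all 12 libraries in the fit edgeR called 16 and 1476. Without uncut replicate 1, 2 or 3 there were 766, 782 and 817 higher and 2543, 2746 and 2906 lower, and 5245 or 5710 were higher without 16 h replicate 1 or 3. In simulated libraries of this comparison, 96% of genes and 50% of regions changed by 4-fold were recovered.

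Regions that were lower than in uncut roots were unevenly spread over the chromosomes. On chromosomes 1, 2 and 4 they made up 10.2%, 7.74% and 9.53% of the regions tested at 2.5 h, 14 h and 16 h, and on chromosomes 3 and 5 4.31%, 1.91% and 2.63%. At 2.5 h, 92.3% of those on chromosomes 1, 2 and 4 and 89.5% of those on chromosomes 3 and 5 had no read in any 2.5 h library. Of 94247 regions above 3 CPM in every uncut library, 1394 had no read in any of the 9 regenerating libraries: 587 on chromosome 1, 594 on chromosome 2, 213 on chromosome 4 and 0 on chromosomes 3 and 5, where 0 of 40305 allows a share of up to 0.00744%. Such floors cover counting error only. Of the 18 named regions that fell against uncut roots, 17 lay in 1 Mb stretches that hold such regions. The region near AT1G06963 counts among the 18 at both 14 h and 16 h. Stretches that hold regions without reads were common: 27 of 31 on chromosome 1, 10 of 20 on chromosome 2 and 18 of 19 on chromosome 4. The 17 therefore say little by themselves. On chromosome 2 the regions without reads ended before 10 Mb, and the highest share of any 1 Mb stretch was 22.8%, on chromosome 1. Regions higher than in uncut roots made up 0.0336%, 0.704% and 3.16% of those on chromosomes 1, 2 and 4 at 2.5 h, 14 h and 16 h, and 0.0634%, 0.849% and 2.95% of those on chromosomes 3 and 5. These shares cannot be compared between times. Regions absent from the uncut set were left out at 2.5 h and 14 h, whereas the 16 h and uncut sets are the same. In the authors' calls, 2971 of 3287 regions higher at 2.5 h and 26055 of 27204 at 14 h lay outside the uncut set.

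**Figure D2:**
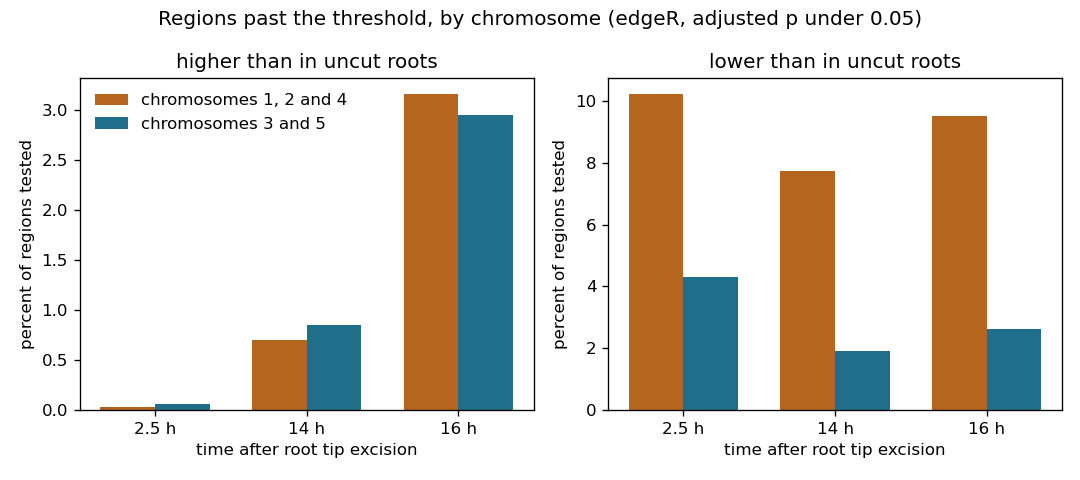
Percent of tested regions past the edgeR threshold (vertical axes) that were higher (left) or lower (right) than in uncut roots at each time, for chromosomes 1, 2 and 4 (brown bars) and chromosomes 3 and 5 (blue bars). At 16 h the bars for lower regions stand at 9.53% and 2.63%. Regions absent from the uncut set were left out at 2.5 h and 14 h, so the bars for higher regions cannot be compared between times.

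**Figure D3:**
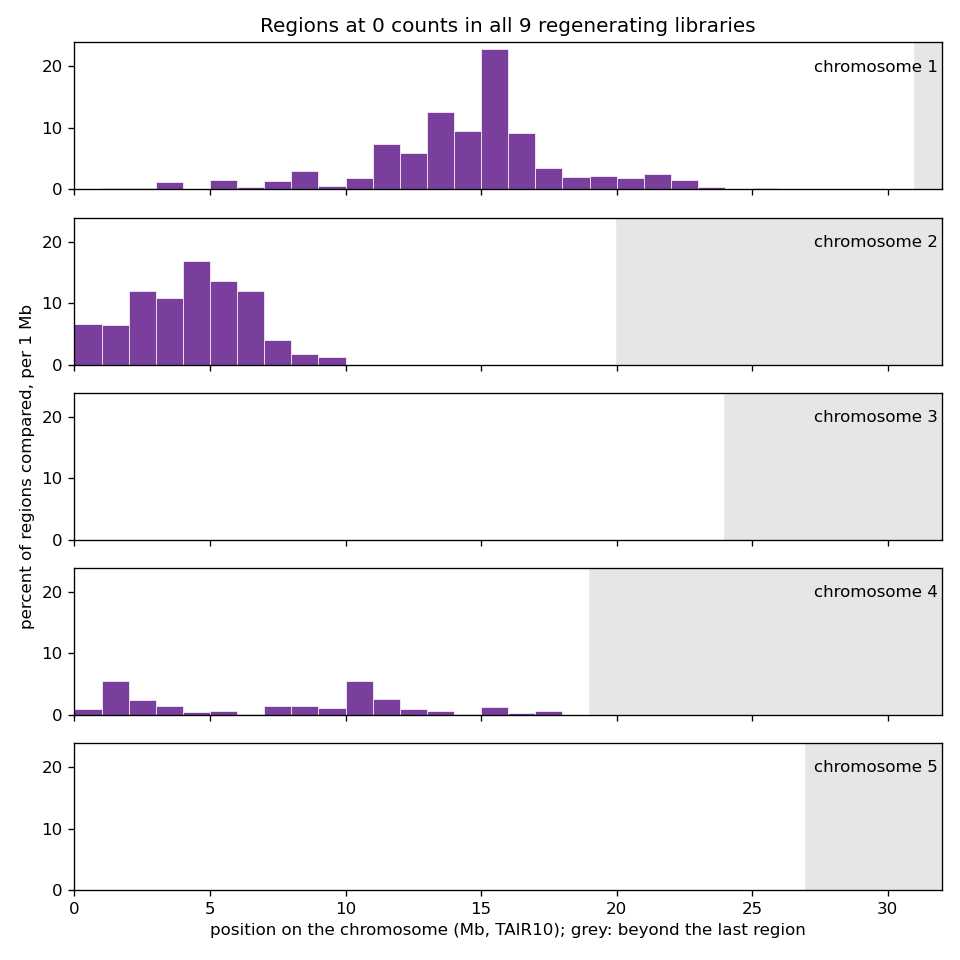
Percent of compared regions with 0 counts in all 9 regenerating libraries (vertical axes) in each 1 Mb stretch of chromosomes 1 to 5 (bars), against position in Mb; grey marks positions beyond the last region. Chromosomes 3 and 5 have no bar, and on chromosome 2 the bars end at 10 Mb.

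Comparisons between times hold the line and the sort constant. MP differed little in level between times, with log2 fold changes of -0.02 ± 0.23 from 2.5 h to 14 h, -0.15 ± 0.28 from 2.5 h to 16 h and -0.11 ± 0.21 from 14 h to 16 h, none past the threshold (edgeR adjusted p = 0.998, 0.9995 and 1.00). From 2.5 h to 14 h, the members with the smallest p were LHCB2.1 (-0.99 ± 0.28) and NUC, a ground tissue factor (0.91 ± 0.27), and from 2.5 h to 16 h NUC (1.12 ± 0.32) and ARR9 (-1.42 ± 0.46), none past the threshold. Between 14 h and 2.5 h, 0 of 92359 regions and 0 of 28000 genes passed edgeR, with 4733 regions and 1450 genes at an unadjusted p under 0.05. DESeq2 called 1414 regions higher and 39 lower, and edgeR with all 12 libraries in the fit 4401 and 94, and without 2.5 h replicate 2 edgeR called 1 higher. Between 16 h and 2.5 h, 0 of 75016 regions and 0 of 27332 genes passed edgeR, with 1708 and 1058 at an unadjusted p under 0.05, against 734 higher and 3 lower by DESeq2 and 4100 and 66 with all 12 libraries in the fit. The fit of all 12 libraries takes a single spread per region over all groups, uncut roots included. Regions without reads in 2.5 h libraries can also appear higher later. The counts from that fit and from DESeq2 therefore need not reflect opening after 2.5 h. In simulated libraries 4-fold changes were recovered in 0% of genes from 2.5 h to 14 h and 8% from 2.5 h to 16 h.

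From 14 h to 16 h, a region in exon 15 of TWN2 (AT1G14610, a valyl-tRNA synthetase, chromosome 1, 5010620 to 5010796) rose by log2 3.53 ± 0.49 (edgeR adjusted p = 0.0425), at 14.96, 10.6 and 7.97 CPM at 14 h and 173, 31.3 and 185 CPM at 16 h. It was the 1 region of 95936 that passed, while 0 were lower and 3195 had an unadjusted p under 0.05. With total counts as library sizes, 16 h replicate 2 held 11.6% of the mean excess of replicates 1 and 3 over uncut roots at TWN2. The source of this unevenness was not tested, so the fold of TWN2 need not measure accessibility. DESeq2 called 1 region higher and 1 lower, TWN2 standing at adjusted p = 0.0687 by that tool. Without 14 h replicate 2 or 3, or 16 h replicate 1 or 3, 0 regions were higher. Of 28181 genes 2 were higher and 0 lower by edgeR, with 1246 at an unadjusted p under 0.05: TWN2 (1.43 ± 0.26) and AT2G41835 (3.34 ± 0.59). The gene count was 0 without 14 h replicate 1, 2 or 3 or 16 h replicate 1, 11 higher and 1 lower without 16 h replicate 2, and 1 without 16 h replicate 3. The stress-response zinc finger gene ZAT12 stood at 48.0 ± 33.2 against 18.6 ± 5.25 CPM, a log2 fold change of 1.40 ± 0.38 that passed adjusted over the list alone (edgeR adjusted p = 0.0256) and not over all genes (1.00).

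In none of the comparisons between times did a list pass camera (lowest adjusted p = 0.671 from 2.5 h to 14 h, 0.805 from 2.5 h to 16 h and 0.631 from 14 h to 16 h), and 0 list members were higher or lower over all genes. Adjusted over the list alone, ZAT12 was the 1 member that passed in any of them. With an estimated correlation in place of the preset, no list passed in any of the 6 comparisons, and the lowest adjusted p values were 0.676, 0.571 and 0.748 against uncut roots and 0.910, 0.929 and 0.767 between times. The test fry, which asks whether a list's members move on balance in 1 direction, passed 1 list, photosynthesis at 14 h (adjusted p = 0.0247). Its mixed form, which asks whether members change in either direction, passed 5, 12 and 14 lists against uncut roots and 1, 0 and 0 between times. Neither form compares a list with the other genes. Against uncut roots, 9.94%, 27.8% and 27.2% of all genes had an unadjusted edgeR p under 0.05. The median, mean and camera direction of a list differed in sign for 5 lists at 2.5 h, among them the cytokinin list (median -0.0041, mean -0.28, camera up), for the stem cell niche, root cap, and endodermis and cortex lists at 14 h, for the stem cell niche and the endodermis and cortex lists at 16 h, and for 6, 5 and 0 lists between times.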

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

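The tests on depth and on closing for the regions without reads, on extra DNA for the chromosome 5 segment and on few fragments at 2.5 h were chosen after the result was seen. The test on chromosome 2 replaced a circular one after these regions and the shares lower on each chromosome were seen, its border at 10 Mb being where they end, and only its own value was then unknown.

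In regions above 3 CPM in each uncut library, 1394 of 94247 had no read in any of the 9 regenerating libraries, and 0 of these lay on chromosomes 3 and 5. Low depth alone would give 1.32e-07 such regions, taking each library's share of zeros from chromosomes 3 and 5, which argues against it. Closing of chromatin after excision, spread as the regions compared, would put 596 on chromosomes 3 and 5, where 0 were found, which argues against it as the whole cause. A candidate explanation is sequence in the MP::MP-GFP line that differs from the reference: on chromosome 2, among regions in or near genes that had reads at 14 h, 3.70% were lower up to 10 Mb and 1.08% beyond, a ratio of 3.42. This is a hypothesis from the same data, since the line and excision change together. The parts of chromosome 2 may also differ in chromatin, and no such contrast of parts was taken on chromosomes 3 and 5. The ratio therefore does not single out a sequence difference. All 18 named regions that fell against uncut roots lay on chromosomes 1, 2 and 4. Of these, 17 lay in 1 Mb stretches with regions without reads, which were common on these chromosomes. A sequence difference stays open for the named regions, and their folds need not measure accessibility. It stays open too for genes of these chromosomes that were lower, LHCB1.1 and LHCB1.2 among them, since their counts are sums over regions there.

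A segment of chromosome 5 (8440307 to 8451086, TAIR10) at AT5G03815, LSU4, LSU2, EMB2820 and AT5G24680 stood at 3.303 ± 0.184 CPM per 100 bp in uncut roots and at 29.0 ± 6.94, 24.1 ± 2.56 and 39.3 ± 6.85 at 2.5 h, 14 h and 16 h (mean ± SD, n = 3), over each group's own regions. The segment was picked at 16 h as a run of regions above every uncut library, which 24 of its 25 regions were, so that all 25 were called higher was largely fixed by this choice. Their log2 fold changes ran from 1.49 to 9.33. Extra DNA of the segment in the GFP line could give an even rise, and the added signal differed by 4.19 times between the 90th and 10th percentile of regions, just past the bound of 4 set for an even rise and far under the one set against it. Opening after excision could give less added signal at 2.5 h than later, and the ratio of 2.5 h to the smaller later value was 1.24, which speaks against it, but the lowest 2.5 h library added 12.5 against a mean of 16.4 at 14 h and the values rest on 4, 3 and 25 regions. That the lowest library should count was decided after the value was seen, and neither explanation is excluded.

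At 2.5 h, regions on chromosomes 3 and 5 that should have 20 or more reads from their uncut level were at 0 in 18.8%, 10.5% and 8.98% of cases, against 0.0218%, 0.518% and 0.0146% in the 16 h libraries, which held 1.69, 2.35 and 1.44 M reads against 4.78, 2.90 and 1.83 M. The lowest of the 2.5 h shares, 8.98%, is consistent with few DNA fragments copied many times. Closing at the same regions would put more regions at 0 in all 3 libraries than chance. Over all 44205 regions compared on chromosomes 3 and 5, 1731 were, against 1603 from the product of the shares at matched uncut level, a ratio of 1.08, which argues against closing as the main source of the zeros. Of the 8412 regions that should have 20 or more reads in each 2.5 h library, 3 were, against 3.51.

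Regions of the 14 h set that are absent from the uncut set were outside the comparisons. With reads recovered from the authors' normalized columns, 25046 of 34687 were higher at 14 h and 157 lower (edgeR). Signal at 14 h decided which regions entered that set, so this direction was largely fixed beforehand and says nothing on opening. Of 101665 regions also in the uncut set, 809 were higher and 15893 lower with the same reads. A difference between 14 h and 16 h put forward the TWN2 region (log2 fold change 3.53), the TWN2 gene (1.43) and the AT2G41835 gene (3.34). At its region on chromosome 2 from 17458405 to 17458571, AT2G41835 stood at 602, 19.3 and 14.0 CPM in the 16 h libraries and at 16.5, 14.7 and 13.8 CPM at 14 h.

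The 6 libraries of a comparison can be split 3 against 3 in 10 ways, so a share of splits cannot fall under 0.1. For regions against uncut roots the real counts were 8042, 6105 and 10410 and the highest other 0, 1 split being as large in each. For genes they were 59, 2983 and 2753 with a highest other of 0, again 1 split each. Between 14 h and 16 h, 1 region passed and at most 0 in the other splits (1 split), and 2 genes passed and 2 in the highest other (2 splits). Counts of 0 between 2.5 h and the later times, and of 0 lists throughout, are reached in 10 of 10 splits whatever the data. They therefore say nothing on chance. The highest other was 0 there except for lists at 16 h against uncut roots (3) and against 14 h (4). Other splits against uncut roots mix uncut and regenerating libraries on a side, which widens the spread, so few calls were likely in them.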

How the results depend on the processing

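Alternatives limited to chromosomes 3 and 5, those on counts of genes, the estimated correlation within 1 kb of a TSS and the recovered reads of all 14 h regions were chosen after seeing the data. Of the counts recomputed, 244 stayed within 1.5 times the reported value and 136 did not. Of the named genes' values 3284 kept direction and side of the threshold, 244 lost and 79 gained the call and 27 reversed, and of the named regions' values 387 kept and 79 lost it. Removing the filter moved no count. Except where fewer regions, genes or libraries were tested, the cause was not tested. GC correction, block with GC, motif tests with their background and window, and organelle regions (0 in the files) were not run. In simulated libraries 4-fold changes were recovered in 0%, 2% and 50% of regions at 2.5 h, 14 h and 16 h against uncut roots.

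Regions higher at 2.5 h numbered 114 with DESeq2 size factors and 224 with total counts. DESeq2 gave 301 higher at 2.5 h, 7289 higher and 11786 lower at 14 h, 8181 higher at 16 h, 1414 and 39 for 14 h against 2.5 h, 734 and 3 for 16 h against 2.5 h, and 1 lower for 16 h against 14 h. Against a fold threshold 6 were higher at 2.5 h, 26 and 3125 passed at 14 h, 832 and 3554 at 16 h, and 0 were higher for 16 h against 14 h. With all 12 libraries in the fit, 18 and 2285 passed at 14 h, 16 and 1476 at 16 h, 4401 and 94 for 14 h against 2.5 h, 4100 and 66 for 16 h against 2.5 h, and 0 were higher for 16 h against 14 h. On chromosomes 3 and 5, with fewer features tested, regions numbered 8 and 1248 at 2.5 h, 25 and 213 at 14 h, 595 and 521 at 16 h, and genes 0 and 0, 197 and 558, and 210 and 329; for 16 h against 14 h 0 regions and 0 genes were higher. Over all 14 h regions with recovered reads 25855 and 16050 passed. Within 1 kb of a TSS, genes numbered 0 and 0 at 2.5 h, 290 and 1085 at 14 h, 577 higher at 16 h and 0 for 16 h against 14 h, and 1 list passed at 14 h, 0 with an estimated correlation.

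Same-numbered replicates did not deviate together (correlations from -0.0345 to 0.0102). The noise of the regenerating libraries could hide a shared batch, so pairing by number is neither shown nor excluded. With the replicate number as a block, regions numbered 0 and 0 at 2.5 h, 99 and 3539 at 14 h, 952 and 4551 at 16 h, 1 higher for 14 h against 2.5 h and 0 for 16 h against 14 h; genes numbered 0 and 22 at 2.5 h, with 389 higher at 14 h, 384 at 16 h and 0 for 16 h against 14 h. The block moved no other count by over 1.5 times. Of the named genes that passed, 9 of 28 at 14 h and 20 of 31 at 16 h did not pass with it.

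Without each library in turn, regions ranged from 0 to 1391 higher and 3420 to 17679 lower at 2.5 h, 38 to 4633 and 2711 to 10227 at 14 h, and 766 to 5710 and 2543 to 8729 at 16 h. Genes ranged from 0 to 477 and 0 to 1382, 25 to 2248 and 879 to 3390, and 88 to 1994 and 572 to 2830. Regions higher ranged from 0 to 1 for 14 h against 2.5 h and for 16 h against 14 h, where genes ranged from 0 to 11 higher and 0 to 1 lower.

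Reversed log2 fold changes, none past the threshold, came within 1 kb of a TSS for EIN3 (AT3G20770, -0.27) and JKD (AT5G03150, 0.26) at 2.5 h; WIND3 (AT1G36060, 0.49), PLT2 (AT1G51190, 0.57), HSP70-4 (AT3G12580, 0.012), BRM (AT2G46020, 0.086) and CMT3 (AT1G69770, -0.022) at 14 h; GH3.2 (AT4G37390, 0.069), PLT2 (0.11), HSP70-4 (0.12) and CMT3 (-0.38) at 16 h; ACS6 (AT4G11280, 1.84), JKD (-0.35) and RGF2 (AT1G13620, 0.057) for 14 h against 2.5 h; and MYC2 (AT1G32640, -0.32), AOC3 (AT3G25780, -0.10), SMB (AT1G79580, 0.23) and MYB36 (AT5G57620, 0.51) for 16 h against 14 h. Leaving out a library, with the range over all left out, reversed LHCA1 (AT3G54890, -0.029 without 2.5 h replicate 1, up to 0.66), HSP17.6II (AT5G12020, 14 h against 2.5 h, -0.71 to 0.049, without 2.5 h replicate 3), HSFB1 (AT4G36990, -0.059 to 1.02 from 2.5 h and -0.21 to 0.87 from 14 h, without 16 h replicate 2) and, for 16 h against 14 h, YUC7 (AT2G33230, -0.048 to 0.59, without 16 h replicate 3), ARF10 (AT2G28350, -0.053 to 0.46, without 16 h replicate 2), SMB (-0.41 to 0.082, without 14 h replicate 3) and BRN2 (AT4G10350, from -0.59, 0.074 without 14 h replicate 2 and 0.11 without 16 h replicate 3).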

Other observations

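Regions between genes made up 15.7% of the annotated regions tested at 2.5 h against uncut roots and 40.1% of those lower, 15.6% and 59.6% at 14 h, and 15.6% and 52.9% at 16 h. Of the regions higher, 8.33%, 11.04% and 9.54% were intergenic. Promoters made up 21.2% of the regions tested at each time, 25%, 27.3% and 24.4% of those higher and 17.63%, 11.7% and 14.2% of those lower. On chromosomes 3 and 5, where no region was at 0 in all 9 regenerating libraries, intergenic regions were 26.6%, 54.9% and 41.8% of those lower. At 16 h the classes cover 2169 of 3310 regions higher and 7025 of 7100 lower. At 2.5 h, 91.6% of the regions lower had no read in any 2.5 h library. The shares by class were examined after the calls were seen, and no test of them was run.

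Across 12050 windows of 5000 bp with 5 or more regions, 3 had a median log2 fold change above 3 at 16 h against uncut roots. Besides the chromosome 5 segment with LSU4 and EMB2820 (6.23 and 3.42), 1 lay on chromosome 4 from 1345001 to 1350000 (TAIR10), with a median of 4.46 over 6 regions.

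In 16 h replicate 2, the U6-26, U6-29 and TWN2 regions stood apart from the other replicates. With total counts as library sizes, U6-26 had 1584, 94.0 and 1882 CPM in replicates 1, 2 and 3, U6-29 2288, 136 and 2981 CPM, and TWN2 156, 26.0 and 167 CPM. Of 33 regions with more than 100 CPM above uncut roots in replicates 1 and 3, 4 had under 25% of that excess in replicate 2.

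The authors' deposited table for 2.5 h lists 3287 regions higher and 9020 lower than uncut roots, all at an adjusted p under 0.05, and 2971 of those higher lie outside the uncut set. The authors' deposited table for 14 h holds 136930 regions, with 27204 higher and 19920 lower at an adjusted p under 0.05, and 26055 of those higher lie outside the uncut set. The authors' deposited table for 16 h holds 30597 regions, with adjusted p up to 0.176, and 8181 higher and 10614 lower at an adjusted p under 0.05, 0 of them outside the uncut set.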
